A study of Arabidopsis thaliana with 4 samples.

How the data were processed

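RNA-seq counts were analysed for 4 libraries of Arabidopsis thaliana embryos in the Col (Columbia) background at the globular stage, when the embryo has 32 to 64 cells. Of these, 2 came from the serrate-1 mutant (se-1) and 2 from wild type, and the series describes them as biological replicates. Per the labels' protocols, the plants were kept at 4 °C in darkness for 4 days or longer and then grown at 22 °C with 16 h of light and 8 h of dark. Total RNA was isolated with the RNAqueous-Micro kit, amplified with the MessageAmp aRNA kit and made into libraries with the TruSeq RNA kit, per the labels' protocols. Amplification of this kind starts from the poly(A) tail, so differences in RNA integrity or in the length of the amplified copies can change the measured level of long against short transcripts.

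The authors deposited a table of raw counts for each library, with whole numbers of reads per gene and no normalization. The submitters' processing notes name FastQC 0.11.5, HISAT2 2.0.5, Cufflinks 2.2.1, featureCounts and the TAIR10 build, without the role or order of each. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads of overlapping genes, of antisense pairs and of near-identical copies (the LHCB1 genes, the LHCB2 genes, the RBCS genes, PHE1 and PHE2) can therefore not be told apart, and their values are uncertain. Each table had 27880 rows. Of their identifiers, 27576 matched the TAIR10.1 annotation, which was used for symbols, biotypes, transcript lengths, exon numbers and overlaps. No coordinates are given, because the tables hold none and the builds are not the same release. In 94 rows the tables join the identifiers of several loci. These rows were tested as they stand and were not counted as any of their loci in the gene lists.

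Total counts per library were 18580516 and 20882004 for se-1 and 18894161 and 19362653 for wild type. Counts of the replicates of a genotype differed by more than sampling noise (chi-square over its degrees of freedom 5.87 for se-1 and 4.10 for wild type, over genes with at least 10 counts), so their tables do not repeat the same counts. Each library was used as a separate replicate because the labels give them as such. CPM values are counts scaled to a common library total after TMM normalization, given as mean ± SD of 2 libraries. Intervals of count ratios are exact 95% intervals and, like the bounds for genes with a count of 0, cover counting error only, since the reads carry no molecular identifiers. A bound takes 3 counts, summed over the group, for a genotype in which both libraries had none. With 2 libraries per genotype, the test of single genes draws on a spread shared across genes.

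Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by genotype, TMM normalization, a quasi-likelihood F-test of se-1 against wild type with no further covariate, two-sided, with Benjamini-Hochberg adjustment at 0.05. This left 18714 genes. The standard error of a log2 fold change was taken as its absolute value divided by the square root of F. All fold changes are se-1 over wild type, and an adjusted p of a single gene comes from this test unless a corrected fit or a replicate block is named. Lists of genes were tested with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the 12 lists with at least 5 members tested. Beside it stand camera with an estimated correlation and fry, which asks whether the members of a list move, on balance, in 1 direction and does not compare them with other genes. Camera with an estimated correlation has few degrees of freedom in 4 libraries, and no list passed with it. The test was run on simulated counts with 200 changed genes drawn from these libraries. Over 18343 genes it called 63.8% of changes of 1.5-fold, 91.7% of changes of 2-fold and 100% of changes of 4-fold and 8-fold. Of unchanged genes 0.0661% were called. In the data 72.3% of tested genes passed, and with so many passing the adjustment admits larger p, so these rates do not carry over.

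The test, 11 gene lists, the annotation rules for MIR genes (which encode the primary transcripts of microRNAs), intronless genes and organelle genes, the rule for the genes named and 14 alternatives were fixed before the data were examined. A rule for transposable element genes was also fixed but gave no usable list, because the annotation holds no such biotype for the counted genes. The genes named are SE, the 12 largest rises and the 12 largest falls among changed genes with a mean of at least 5 CPM whose groups do not overlap, and up to 4 members of each list with the smallest adjusted p. Other members named as examples were chosen after their values were seen. The alternatives were DESeq2 size factors, library size alone, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 1 CPM in 2 libraries, a replicate block, each library left out, a test against a 1.5-fold change, camera with an estimated correlation and fry.

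A relation between fold change and transcript length was found in the data, and the following were then added: bins of transcript length, 3 corrected fits and random lists. Exonic length was that of the longest annotated transcript. The length-corrected fit used offsets for each library from a natural spline with 5 degrees of freedom of log2 exonic length, learned on nuclear protein-coding genes; features shorter or longer than the 1st or 99th percentile of those genes took the trend at that percentile. The others added a spline of GC content or a replicate block. In simulated counts with such a trend, the fit without correction called 53.2% of unchanged genes and the corrected fit 0.393%, over 18448 and 18266 genes. The simulated trend was linear in log2 length, a form the spline can follow, so this shows only that such a trend is removed. Each list median was also set against 10000 random lists of the same size matched on length and expression. Genes of a random list were drawn independently, whereas members of a gene list can move together. The central 95% of random lists can therefore be too narrow for such a list. Intervals of medians are 95% intervals from order statistics. Counts of MIR genes by family, lists of genes induced by iron deficiency and by mitochondrial dysfunction, and counts per chromosome were also added after the data were seen.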

Results

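The series compared gene expression in globular-stage embryos of wild-type Arabidopsis and of the se-1 mutant. SERRATE (SE) is a zinc-finger protein that works with the nuclease DCL1 and the double-stranded RNA-binding protein HYL1 in cutting microRNAs out of their primary transcripts, and it also takes part in mRNA splicing. se-1 is a partial loss-of-function allele. Between 18580516 and 20882004 reads were counted per library, in 2 libraries per genotype. Genes with at least 1 count numbered 22062.5 ± 135 (SD, n = 2) in se-1 and 23352 ± 63.6 (SD, n = 2) in wild type.

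The SE transcript (AT2G27100) stood at 69.4 and 71.1 CPM in the se-1 libraries and at 96.7 and 98.6 CPM in the wild-type libraries. It was 1.39-fold lower in se-1 (log2 fold change -0.48, SE of the fold change 0.079, adjusted p = 2.9e-05, edgeR). After correction for transcript length the log2 fold change was -0.18 (adjusted p = 0.0563), and after correction for length and GC content -0.35 (adjusted p = 8.0e-04). A partial loss-of-function allele need not lower its own transcript, so this level is no check of the labels.

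Primary microRNA transcripts were higher in se-1 embryos, with a median log2 fold change of 2.55 over the 33 MIR genes tested, or 1.42 after correction for transcript length. Nuclear photosynthesis genes rose together to 3.01-fold the wild-type sum, while transcripts of the chloroplast genome fell to 0.494 of their wild-type share. DNA replication genes were lower, 11 of 12 passing the test, or 9 after length correction. The RNA silencing genes AGO4 and RDR2 were 2.97-fold and 3.04-fold lower. After length correction their log2 fold changes were -1.06 and -0.97. Of 67 known microRNA target genes 33 were higher and 14 lower, or 37 and 6 after length correction. Some single genes changed by far more, among them AT1G47395, 533-fold higher, and MRD1, 249-fold lower.

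The genotypes differed across most of the transcriptome. Of the 18714 genes tested, 13523 (72.3%) changed, 6777 higher and 6746 lower in se-1 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). At least 2-fold changes numbered 2760 upward and 1852 downward, and at least 4-fold changes 804 and 364. The genotypes did not overlap in 85.5% of tested genes, where chance alone gives 33.3%. Across genes, the correlation of log2 CPM was 0.995 between the se-1 replicates and 0.995 between the wild-type replicates, and 0.914 to 0.918 between genotypes. The first principal component held 93.8% of the variance. The biological coefficient of variation was 0.0579, so small differences passed the test. The labels name no batch, and the genotype cannot be separated from any other difference between the 2 sets of samples.

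Short transcripts were higher and long transcripts lower in se-1. Protein-coding genes of 300 to 500 nt had a median log2 fold change of 1.26 (218 genes) and those of 500 to 750 nt of 1.11 (704 genes), against -0.82 at 4000 to 5000 nt (478 genes) and -0.99 above 5000 nt (278 genes). The shortest class, up to 300 nt, did not follow this order, with a median of 0.06 over 52 genes. Across 18495 coding genes, which are not independent replicates, Spearman's rho of log2 fold change against length was -0.434, and a spline of length took up 13.3% of the variance of fold changes (R2 = 0.133). Between replicates of a genotype rho was -0.0235 for se-1 and -0.105 for wild type. The median length over counted reads was 1690.5 ± 4.95 nt (SD, n = 2) in se-1 and 1813.5 ± 6.36 nt (SD, n = 2) in wild type. With the trend removed, 12357 of 18529 genes changed (6014 higher, 6343 lower). At least 2-fold changes then numbered 1907 upward and 1671 downward. Of the genes called in both fits, 10239 had the same sign and 376 the opposite sign. Among genes tested in both, 2766 were called only without the correction and 1742 only with it. Length-corrected values are therefore given beside the gene lists. Whether the trend is technical or biological was not tested, so the correction may also remove part of a real difference between the genotypes.

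**Figure D1:**
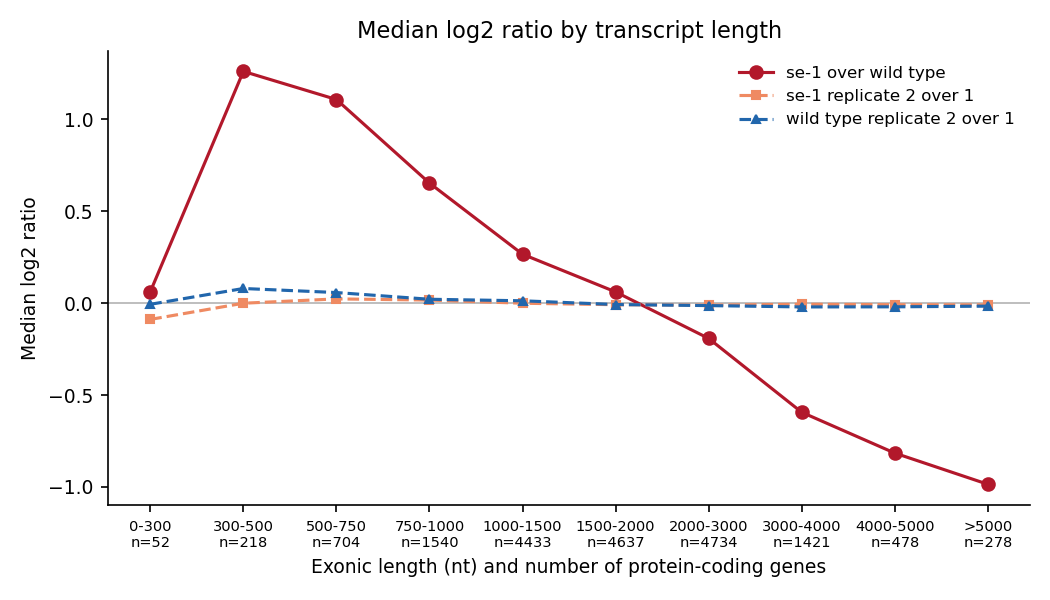
Median log2 ratio of protein-coding genes (y axis) by exonic length in nt (x axis, with the number of genes per class) for se-1 over wild type and for replicate 2 over replicate 1 within each genotype. The ratio between genotypes goes from 1.26 at 300 to 500 nt to -0.99 above 5000 nt, while the ratios within genotypes stay between -0.09 and 0.08.

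The largest fitted rise among genes above the expression minimum was that of NAC085 (AT5G14490), a NAC transcription factor. It stood at 20.2 ± 1.98 CPM in se-1 with a single count in the wild-type libraries (ratio of counts 768, exact 95% interval 137 to 30370). The interval of AT1G47395 (ratio 568, 221.5 to 2086) lies inside that of NAC085, so the counts do not order them. AT1G47395, a small peptide gene of iron deficiency signalling known as IMA2, stood at 59.4 ± 6.73 CPM against 0.105 ± 0.00053 CPM (log2 fold change 9.06, SE 0.22, adjusted p = 4.4e-16), and FRO3 (AT1G23020), a mitochondrial ferric reductase, was 105-fold higher (adjusted p = 5.6e-16). NDB4 (AT2G20800), an alternative NADH dehydrogenase of mitochondria, rose 174-fold to 87.7 ± 9.80 CPM (adjusted p = 1.6e-16). AT2G18193, annotated as a nucleoside triphosphate hydrolase, rose 82.1-fold, the glycine-rich protein gene GRP-3 (AT2G05520) 58.8-fold, the pectin methylesterase gene ATPMEPCRD (AT2G43050) 41.7-fold and the lipid transfer protein gene LTP2 (AT2G38530) 39.5-fold, the last to 353 ± 15.0 CPM. The others were AT3G45730 (ratio of counts 143, interval 48.7 to 697, 3 wild-type counts), the mitochondrial-genome gene ATMG00030 (63.1-fold), AT5G55270 (61.8-fold) and AT7SL-1 (AT4G02970), a gene for the RNA of the signal recognition particle (52.8-fold).

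Among genes above the same expression minimum, the largest fall was that of MRD1 (AT1G53480). It stood at 0.459 ± 0.107 CPM in se-1 and 115 ± 0.608 CPM in wild type, 249-fold lower (log2 fold change -7.96, SE 0.16, adjusted p = 4.0e-17). The beta-glucosidase gene BGLU28 (AT2G44460) was 15.0-fold, the glycosyl hydrolase gene GH9B9 (AT2G44540) 9.75-fold and the beta-amylase gene BAM5 (AT4G15210) 9.39-fold lower, BAM5 from 263 ± 2.77 CPM. The copper amine oxidase gene AT3G43670 was 9.47-fold lower, the tetraspanin gene TET11 (AT1G18520) 8.24-fold, AT2G16760 6.41-fold, FIS2 (AT2G35670), a Polycomb gene of the endosperm, 5.93-fold and AT5G45095 5.86-fold. The chloroplast-genome genes ATCG00770 and ATCG00340 were 9.38-fold and 6.27-fold lower, and another chloroplast gene 7.44-fold.

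Of 224 MIR genes in the tables, 33 had enough counts to be tested. In se-1, 29 rose and 2 fell (camera adjusted p = 1.03e-07). The set call did not hold with an estimated correlation (adjusted p = 0.244). MIR168a rose from 13.1 ± 0.862 to 163 ± 9.78 CPM (log2 fold change 3.64, SE 0.098), MIR156c from 23.1 ± 3.57 to 279 ± 26.8 CPM (3.59, SE 0.11), MIR390a from 2.2 ± 0.508 to 31.5 ± 0.173 CPM (3.83, SE 0.14) and MIR159b from 4.15 ± 0.202 to 24.2 ± 0.466 CPM (2.55, SE 0.12), each with an adjusted p of 2.1e-12 or less. MIR168a, MIR156c, MIR390a and MIR159b were at 2.51, 2.46, 2.70 and 1.42 on the log2 scale after length correction. The summed level of the tested MIR genes was 834 ± 71.6 CPM in se-1 and 151 ± 4.81 CPM in wild type, 5.53-fold higher. All 23 MIR genes that overlap no annotated gene rose, with a median log2 fold change of 3.28 (95% interval 1.94 to 3.83). Of the 10 that overlap another gene, 6 rose and 2 fell. Those that fell were MIR839, with 2 counts in se-1 against 42 (ratio 0.0459, exact 95% interval 0.00538 to 0.176), and MIR5029, with no count in se-1, at least 10.7-fold lower against 31 counts. After length correction 23 MIR genes were higher and 4 lower, with a median of 1.42 (95% interval 0.54 to 2.47). The annotated MIR genes are precursor hairpins with a median of 138 nt, and their correction takes the trend at the short end of coding genes. Coding genes of up to 300 nt had a median log2 fold change of 0.06. Whether the correction holds for features this short was not tested. Rows that join a MIR gene to a neighbour are outside these counts. IQD20 with MIR171a rose from 19.9 to 251 CPM, MIR167b with AT3G63380 had a log2 fold change of 2.90, LIG6 with MIR163 had -1.61, and DCL1 with MIR838 had -0.55 (adjusted p = 1.4e-05).

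**Figure D2:**
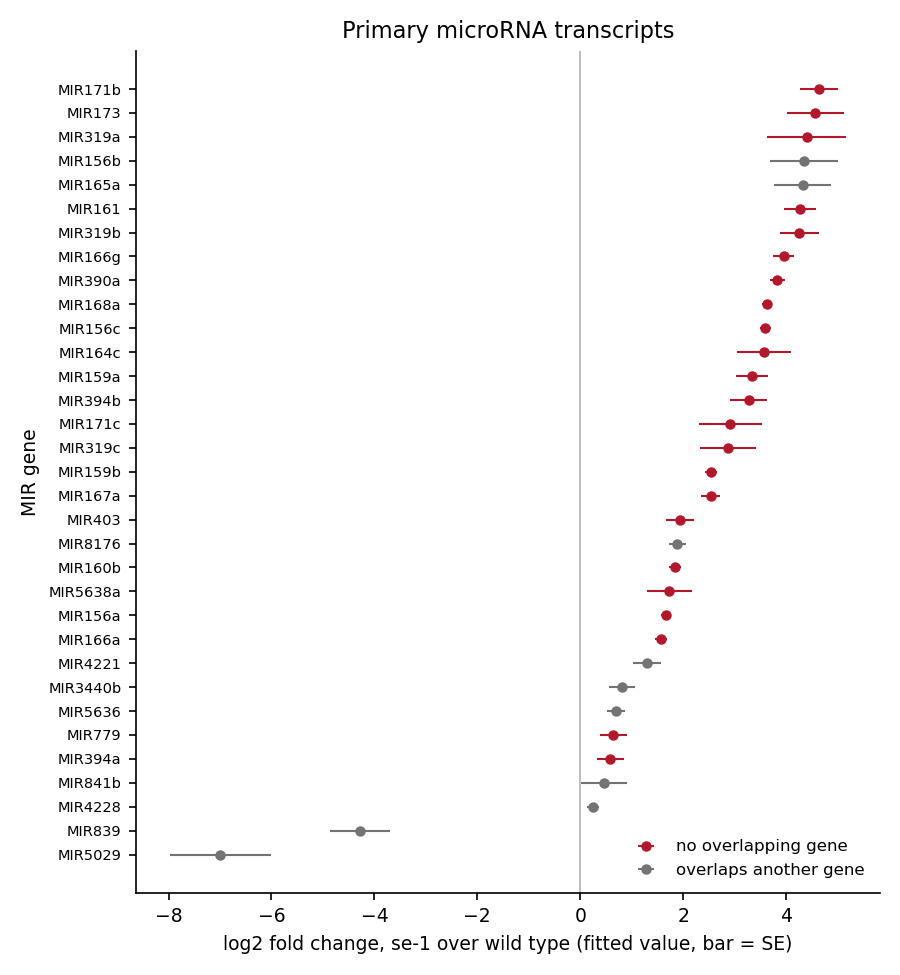
Fitted log2 fold change of the 33 tested MIR genes, se-1 over wild type (x axis), with bars of 1 SE and colour marking overlap with another annotated gene. All 23 genes without overlap lie above 0, and the 2 that fell overlap another gene.

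Among the 67 tested members of the list of known microRNA targets, 33 rose, 14 fell and 20 did not pass. The median log2 fold change was 0.24 (95% interval 0.06 to 0.46), and the list did not pass (camera adjusted p = 0.0751). Without se-1 replicate 1 it passed (adjusted p = 0.0423), as it did after length correction (adjusted p = 8.69e-04, median 0.40, 37 higher and 6 lower). With an estimated correlation it did not (adjusted p = 0.338). All 3 tested targets of miR398 rose, among them the genes of the copper/zinc superoxide dismutases CSD2 (AT2G28190) 3.05-fold higher at 170 ± 11.3 CPM (SE of the log2 fold change 0.087, adjusted p = 1.1e-11) and CSD1 (AT1G08830) 2.54-fold higher. After length correction CSD2 was at 1.1 and CSD1 at 0.65 on the log2 scale, and CCS1, the other target, did not pass (adjusted p = 0.983). NF-YA1 (AT5G12840), a target of miR169, rose 2.37-fold, and bHLH74 (AT1G10120), a target of miR396, rose 2.51-fold. All 4 tested targets of miR164 rose, among them the boundary genes CUC1 (1.88-fold) and CUC2 (1.26-fold), at 0.60 and 0.19 on the log2 scale after length correction, and so did all 3 of miR172, the AP2-type genes AP2, TOE1 and TOE2 (1.41-fold to 1.68-fold), which were also higher after length correction. SPL11, a target of miR156, rose 4.95-fold from 1.37 ± 0.0673 CPM. Of the class III HD-ZIP targets of miR165 and its relatives none rose, with REV, PHB and ATHB15 lower and PHV (log2 fold change -0.11) and ATHB8 (-0.18) not passing. REV was 2.13-fold lower and remained lower after length correction (log2 fold change -1.09 before, -0.50 after), whereas PHB and ATHB15 were at 0.04 and 0.04 after it, ATHB8 was at 0.30 without passing, and PHV was higher at 0.35 (adjusted p = 7.0e-04). AGO1, the target of miR168, fell 1.84-fold (log2 fold change -0.88, or -0.27 after length correction).

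Targets of trans-acting siRNAs were represented by 3 auxin response factors, too few for a set test, and their precursors had no row. ARF3 (AT2G33860) rose 2.17-fold to 575 ± 18.6 CPM (adjusted p = 7.8e-10). ARF2 (AT5G62000) was 1.93-fold lower, from 329 ± 7.39 CPM, and ARF4 (AT5G60450) 1.63-fold lower. After length correction ARF3 was at 1.31, ARF2 at -0.29 and ARF4 at -0.19 (adjusted p = 0.0584 for ARF4).

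Of 22 genes of the small RNA machinery, 17 fell and 3 rose (median log2 fold change -0.69, camera adjusted p = 0.0018). The call did not hold with an estimated correlation (adjusted p = 0.244) or after length correction (adjusted p = 0.431, 9 lower and 5 higher), and these genes have a median length of 3350 nt. Of 10 genes of siRNA pathways 9 fell, or 5 with 2 higher after length correction. Among those that act in siRNA-directed DNA methylation, AGO4 (AT2G27040) stood at 212 ± 9.65 against 629 ± 0.469 CPM (2.97-fold lower, adjusted p = 9.8e-12), and RDR2 (AT4G11130) was 3.04-fold and DCL3 (AT3G43920) 2.66-fold lower. Their log2 fold changes after length correction were -1.06, -0.97 and -0.56. The exportin gene HST (AT3G05040) fell 2.25-fold (log2 fold change -0.45 after length correction). HYL1 rose 2.04-fold, from 14.7 ± 0.928 to 30.0 ± 1.53 CPM.

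Regulators of embryo patterning went both ways, with 15 of 41 higher, 16 lower and 10 not passing, and the list did not pass against other genes (median log2 fold change -0.11, camera adjusted p = 0.731). WOX8 (AT5G45980), a homeobox gene of the basal lineage and suspensor, fell from 68.3 ± 2.98 to 23.6 ± 1.55 CPM (2.89-fold lower, SE of the log2 fold change 0.089, adjusted p = 3.3e-11). GN (AT1G13980), a regulator of vesicle traffic that positions PIN proteins, fell 2.86-fold (log2 fold change -1.52, or -0.67 after length correction) and REV (AT5G60690) 2.13-fold. In the apical group 10 of 19 rose and 4 fell, including rises of CUC1 (AT3G15170) to 173 ± 5.85 CPM, of the AP2-type gene DRN (3.35-fold) and of WOX2 (2.55-fold). Both epidermal regulators, ATML1 and PDF2, fell by 0.82 and 0.72 on the log2 scale. After length correction the list had 14 higher and 10 lower (camera adjusted p = 0.498), ATML1 was at -0.14 (adjusted p = 0.161), PDF2 at -0.20 (adjusted p = 0.0404) and WOX8 at -1.94, and in the apical group 8 were higher and 2 lower.

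In the seed maturation list 9 of 18 tested members rose and 3 fell, without passing as a list (camera adjusted p = 0.0751; 0.498 after length correction). All 6 tested storage genes rose, among them OLEO4 (AT3G27660, an oleosin of oil bodies, 3.81-fold) and OLEO2 (AT5G40420) from 105 ± 3.59 to 252 ± 0.874 CPM (log2 fold change 1.26, or 0.62 after length correction). SESA2, a seed storage albumin, was at least 24.4-fold higher, with 76 counts in se-1 and none in wild type. The full list holds 29 genes, and those not tested were all storage genes. A gene with almost no wild-type counts, such as SESA2, can be tested only if it is higher in se-1. The common rise of the tested storage genes may thus be partly set by the filter. After length correction 4 of these 6 were higher and 1 lower. Of the 12 regulators 3 rose and 3 fell. L1L (AT5G47670), a NF-YB subunit related to LEC1, rose 2.5-fold, and MYB118 (AT3G27785), a repressor of maturation genes in the endosperm, fell from 222 ± 8.32 to 43.6 ± 0.226 CPM (5.10-fold lower, adjusted p = 4.0e-14), along with its relative MYB115 (11.8-fold lower, from 1.86 CPM).

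Cell cycle genes were lower as a list, with 19 of 30 lower and 4 higher (median log2 fold change -0.36, camera adjusted p = 0.0073; 0.0184 after length correction). With an estimated correlation the adjusted p was 0.413. The central 95% of matched random lists had medians of -0.35 to 0.17. Replication genes accounted for 11 of the falls. MCM4 (AT2G16440) and MCM5 (AT2G07690), subunits of the replicative helicase, were 2.41-fold and 2.30-fold lower, MCM4 at 221 ± 0.789 against 534 ± 22.6 CPM. PCNA1 (AT1G07370), the sliding clamp, was 1.92-fold lower (adjusted p = 1.7e-08). After length correction 9 of the 12 replication genes were lower and none higher. Mitotic genes were mixed, 8 of 18 lower and 4 higher, or 9 and 3 after length correction, with CYCB1;4 (AT2G26760) 2.47-fold lower and CDKB2;1 1.77-fold higher.

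Nuclear photosynthesis genes rose, 29 of 31, with none lower (median log2 fold change 1.44, 95% interval 1.22 to 1.91, camera adjusted p = 1.9e-09). With an estimated correlation the adjusted p was 0.244. All 15 antenna genes rose and were also higher after length correction, including LHCB2.2 (AT2G05070) from 3.75 ± 0.204 to 68.6 ± 4.76 CPM (18.3-fold), LHCB2.1 (AT2G05100) 5.88-fold, LHCB1.5 (AT2G34420) 5.14-fold to 545 ± 24.3 CPM and LHCB3 (AT5G54270) 4.55-fold. RBCS1A, a small subunit of Rubisco, rose 3.65-fold to 2065 ± 565 CPM. The genes that did not pass were PSAD1 and GLK2. The median exceeded that of all 10000 random lists and was 1.26 after length correction (95% interval 0.96 to 1.46, 28 higher and 1 lower). The summed level was 8044 ± 349 CPM in se-1 and 2673 ± 100 CPM in wild type. Chloroplast-genome transcripts took 0.390 ± 0.0087% of the counts in se-1 and 0.790 ± 0.0207% in wild type, and 58 of 73 tested chloroplast genes fell while 4 rose. Mitochondrial-genome transcripts took 0.0136 ± 0.00018% in se-1 and 0.00992 ± 0.000072% in wild type, with 9 of 29 genes higher and 9 lower. The median log2 fold change of these genes was -0.15, so the larger share was not a common rise. ATMG00030 alone went from 0.446 ± 0.114 CPM in wild type to 28.5 ± 1.88 CPM in se-1.

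**Figure D3:**
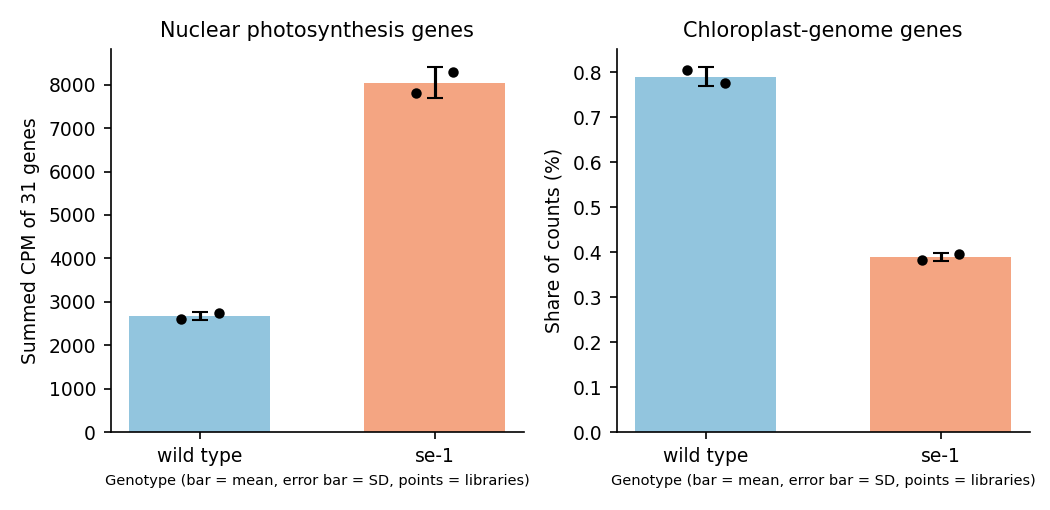
Summed CPM of 31 nuclear photosynthesis genes (left) and percent of counts from chloroplast-genome genes (right) in wild type and se-1, with bars for means, error bars for the SD and points for the 2 libraries of each genotype. The nuclear sum is 8044 in se-1 against 2673 CPM in wild type, and the chloroplast share is 0.390% against 0.790%.

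Auxin response and synthesis genes were higher, with 12 of 17 up and 2 down (median log2 fold change 0.77, camera adjusted p = 0.0212). The list did not pass with an estimated correlation (adjusted p = 0.330), without se-1 replicate 2 (adjusted p = 0.0548), with DESeq2 (0.179), with no filter on low counts (0.0652) or after length correction (0.130), while its median lay above the -0.31 to 0.56 of the central 95% of matched random lists. GH3.1 (AT2G14960), an auxin-conjugating enzyme, rose 8.92-fold from 1.1 ± 0.366 CPM, GH3.3 (AT2G23170) 2.1-fold, GH3.2 (AT4G37390) 1.79-fold to 181 ± 1.37 CPM and IAA4 (AT5G43700) 2.39-fold. Among genes of auxin synthesis YUC1, YUC4, YUC8 and TAA1 rose, and YUC3 fell 2.02-fold. Of 17 stress genes 9 rose and 4 fell, without passing as a list (camera adjusted p = 0.0542; 0.241 after length correction), although it passed with a filter of at least 1 CPM in 2 libraries (adjusted p = 0.0494). TCH4 (AT5G57560), a touch-induced cell wall enzyme, rose 2.62-fold, HSFA2 (AT2G26150) 2.67-fold, PDC1 (AT4G33070) 1.84-fold and HSP70-4 (AT3G12580) 1.84-fold, whereas HSP90.1 fell 1.58-fold and WRKY40 3.14-fold.

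Markers of the surrounding seed tissues moved in both directions. Of 16 endosperm markers 9 rose and 5 fell (camera adjusted p = 0.358; 0.731 after length correction), with PHE1 (AT1G65330) 7.45-fold and PHE2 (AT1G65300) 5.22-fold higher, and FIS2 5.93-fold and FWA (AT4G25530) 1.80-fold lower. Their median was above 0 (0.72), but their summed level was 199 ± 6.65 CPM in se-1 and 205 ± 6.23 CPM in wild type, a ratio of 0.972 that lies within the spread of the libraries. Outside this list MYB118, the endosperm gene named above, fell from 222 to 43.6 CPM. The sum therefore does not show that endosperm content was equal. Of 22 seed coat markers 12 rose and 6 fell (camera adjusted p = 0.221; 0.498 after length correction). The laccase gene TT10 (AT5G48100) rose 3.49-fold, SHP2 (AT2G42830) 2.78-fold and TT7 (AT5G07990) 1.70-fold, and STK (AT4G09960) fell 2.2-fold. Their summed level was 2239 ± 9.12 CPM in se-1 and 2151 ± 8.71 CPM in wild type, a ratio of 1.04.

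Intronless genes were compared because SE also acts in splicing. Of 2338 intronless protein-coding genes 1063 rose and 646 fell, with a median log2 fold change of 0.25 against -0.02 for 16157 genes with introns (camera adjusted p = 0.0212). The call did not hold with an estimated correlation (adjusted p = 0.362), with DESeq2 (0.194), with no filter on low counts (0.172) or after length correction (0.537), where the medians were 0.05 and -0.03. Against random lists matched on length and expression the median of 0.25 still lay above the central 95% (0.14 to 0.23). Intronless genes were shorter, with a median of 1401 nt against 1787 nt. Those with the smallest adjusted p were AT1G47395, AT1G68440 (12.2-fold higher at 280 ± 26.9 CPM), AT5G05250 (11.2-fold) and AT3G56360 (10.5-fold), the last 3 annotated as uncharacterized proteins. In each of the 12 lists the counts of higher and lower genes adjusted over the list alone equalled those adjusted over all genes.

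**Figure D4:**
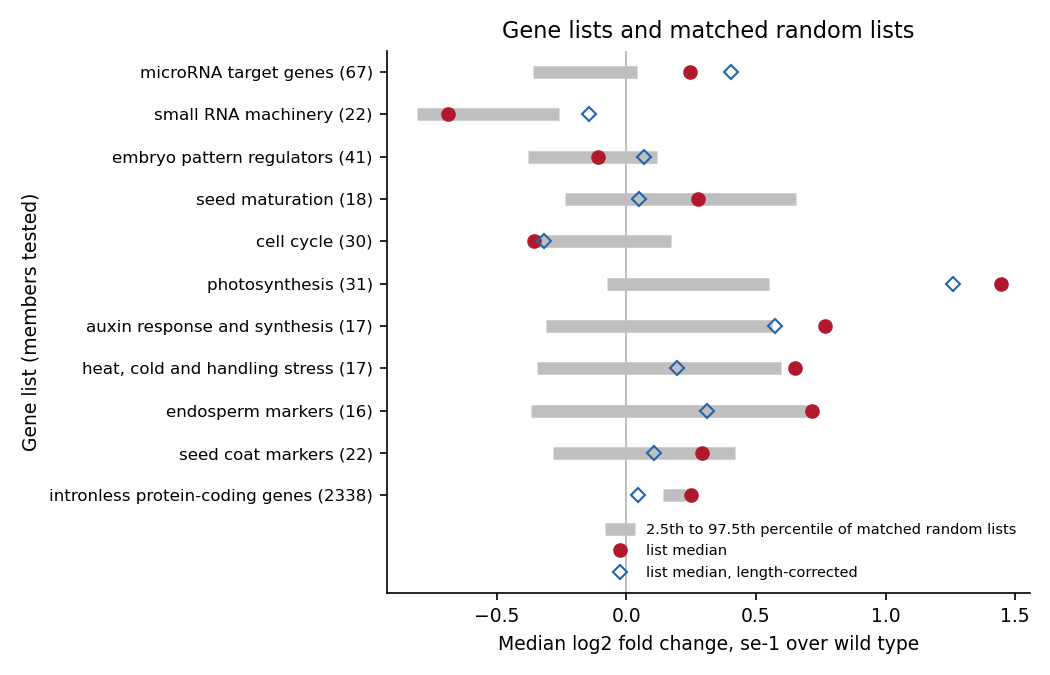
Median log2 fold change of each gene list, se-1 over wild type (x axis), as fitted (filled circles) and after length correction (open diamonds), with grey bars for the central 95% of 10000 random lists matched on length and expression. The fitted medians of photosynthesis (1.44), auxin (0.77), endosperm (0.72), stress (0.65), intronless (0.25) and microRNA target genes (0.24) lie above their bars, which end at 0.55, 0.56, 0.71, 0.60, 0.23 and 0.04, and that of cell cycle genes (-0.36) lies below its bar, which starts at -0.35.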

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

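Of the alternatives given here, those with correction for transcript length or GC content were chosen after the results were seen. Between 11114 (DESeq2) and 13683 (replicate block) genes changed under the alternatives to the 13523, except that a test against a 1.5-fold change, a stricter question, gave 6266 (3413 higher, 2853 lower). With the replicate block, 6843 were higher and 6840 lower. Same-numbered libraries did not deviate together (correlation 0.0263), so the data gave no sign that the numbers pair them. The labels do not say whether a number marks a shared day or batch. The block changed no call of a list. All 74 named genes kept direction and call under the other normalizations, tools and filters and in the replicate block, and kept direction with each library left out. The test against a 1.5-fold change was run for the counts of genes and not for these. Apart from SE, these genes were picked from the same libraries for large changes or small adjusted p, so their stability was likely beforehand. After length correction 68 of the 70 with a length kept direction and call. The exceptions were ARF4 and SE, and the log2 fold change of SE became -0.18 with and without the block (adjusted p = 0.0599 and 0.0563). After correction for length and GC content 69 of the 70 kept direction and call, and SE was lower (-0.35, adjusted p = 8.0e-04).

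The microRNA target list passed with a 1 CPM filter (adjusted p = 0.0494, median 0.29), after correction for length (8.69e-04, median 0.40), for length and GC (0.0032, median 0.40) and for length in the replicate block (8.61e-04, median 0.40), and with fry (0.00549). With single libraries left out its p ran from 0.0423 to 0.0897 and its median from 0.18 to 0.35. Such fits leave 1 library in a group, which is assumed to vary like the other group. The small RNA machinery did not pass after the same 3 corrections (0.431, 0.353 and 0.460), the intronless genes did not (0.537, 0.754 and 0.521, and 0.194 with DESeq2, 0.172 unfiltered), and auxin genes did not (0.130, 0.167 and 0.102, and 0.179 with DESeq2, 0.0652 unfiltered). With single libraries left out the auxin p ran from 0.0145 to 0.0548. The cause was not tested beyond length.

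With an estimated correlation no list passed, and calls were lost for the small RNA machinery, photosynthesis and MIR genes (0.244 each), cell cycle (0.413), auxin (0.330) and intronless genes (0.362). This setting leaves few degrees of freedom with 4 libraries. The estimated correlation of the small RNA machinery was -0.026 and that of auxin genes -0.031, both below the preset 0.01. Fry, which does not compare a list with other genes, also passed embryo pattern (0.032), maturation (0.0060), stress (0.0060), endosperm (0.00962) and seed coat genes (0.0329), and stress passed with a 1 CPM filter (0.0494). Of 224 MIR genes 33 had enough counts to be tested, and whether depth or low expression limits the others was not tested.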

Other observations

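Chosen only after results were seen were the tests of photosynthesis genes against green tissue and of MIR genes without overlap against length, the length-corrected fits, the random lists, the lists of genes induced by mitochondrial dysfunction and by iron deficiency, the MIR families and the counts per chromosome.

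Genes known to be induced when mitochondria fail formed a further group that was higher in se-1. The list used holds 21 such genes, to which NDB4 does not belong, and 14 of them were tested. Of these, 13 rose and none fell. Their median log2 fold change was 1.85, against -0.35 to 0.76 for the central 95% of random lists. The random lists do not carry the shared regulation of such genes. The alternative oxidase gene AOX1A rose 10.6-fold, from 5.54 ± 0.659 to 58.8 ± 1.16 CPM. At12Cys-2 rose 14.0-fold to 134 ± 7.78 CPM, the mitochondrial heat shock gene HSP23.5 17.0-fold and UPOX1 11.9-fold, and among regulators CRF6 rose 7.15-fold and NAC013 2.81-fold. AT1G05060 did not pass (log2 fold change 0.23, adjusted p = 0.209). After length correction 12 were higher and none lower, with a median of 1.97.

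Genes raised by at least 16-fold lay on chromosome 2 more often than tested genes did, at 34 of 116 (29.3%) against 15.2% (two-sided Fisher's exact test, p = 1.2e-04, adjusted p = 0.00489 over 40 comparisons). At 8-fold the share was 22.3% (adjusted p = 0.0282), at 4-fold 15.1% (adjusted p = 1), and no chromosome had an excess of lower genes. The test treats neighbouring genes as independent, and genes past a higher threshold are counted again at the lower ones. SE (AT2G27100) itself lies on chromosome 2, and whether the excess is tied to its position was not tested.

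MIR genes of the families in the target list, with miR390 and miR394, all rose (21 of 21), and of the other 12, most of which overlap another gene, 8 rose and 2 fell. After length correction 20 of the 21 were higher and none lower (median 2.22), and of the other 12, 3 were higher and 4 lower (median -0.37).

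MIR genes were higher in se-1, and the values argue against 2 accounts of this for those that overlap no other gene. Against reads of overlapping genes stands a median log2 fold change of 3.276 over the 23 genes without overlap, and against the length trend as the whole cause stands their median of 2.159 after correction (95% interval 0.81 to 2.70). Over all 33 genes the length trend stays open, because the interval of the corrected median of 1.416 reaches down to 0.54. That correction takes the trend at the short end of coding genes, and whether it holds for hairpins was not tested. Lower conversion of primary transcripts to microRNA may account for the rise. The median of known targets exceeded 99.98% of random lists matched on length and expression, although small RNAs were not measured. Without length correction the targets did not pass as a list in the test fixed in advance, and they passed in only some of its alternatives. Single targets went both ways, with 37 higher and 6 lower after length correction. MIR171b rose 25.1-fold and MIR168a 12.4-fold, yet their tested targets HAM1, HAM2 and AGO1 were lower. After length correction HAM2 (log2 fold change -0.42) and AGO1 (-0.27) remained lower, and HAM1 (0.03) did not pass.

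Nuclear photosynthesis genes were higher in se-1 and the corrected median of 1.26 (95% interval 0.96 to 1.46) argues against the length trend as the whole cause. Green tissue carried along with the embryos would bring chloroplast transcripts, yet their share in se-1 was 0.494 of that in wild type and lower in both se-1 libraries. Because amplification started from the poly(A) tail, this share need not follow the amount of chloroplast RNA. It therefore does not decide whether such tissue was present, and a separate loss of organelle RNA in the se-1 samples was not tested. The genotype, carried-along tissue and a difference in embryo age between the samples may each account for the rise, and the design does not separate them.

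Iron-related genes stood among the largest rises, and an iron deficiency response may account for part of them. Without FRO3 and AT1G47395, which raised the question, 10 of 16 tested genes known to be induced by iron deficiency rose and 3 fell, with a median of 0.83 that exceeded 99.78% of random lists. Of the 19 genes in this list, bHLH38, bHLH101 and IRT1 did not enter the test. The regulators bHLH100 (38.3-fold, from 0.210 to 8.30 CPM) and bHLH39 (191 counts against 1, ratio 184, exact 95% interval 32.6 to 7306) rose, IMA1 was at least 64.6-fold and IMA3 at least 8.03-fold higher, and the transporter gene OPT3 rose 3.17-fold. IMA1, IMA3 and bHLH39 had at most 1 wild-type count and entered the test only through their se-1 counts. Against a plain deficiency, FIT fell 6.01-fold and the ferritin gene FER1 rose 3.24-fold, while FER3 and FER4 fell by 0.20 and 0.34 on the log2 scale. FIT was low in both genotypes, at 0.368 ± 0.293 CPM in se-1 and 2.31 ± 0.0117 CPM in wild type. No further explanation was tested beyond length, after which 11 of the 16 were higher and 1 lower.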
